A study of Drosophila melanogaster with 4 samples.

How the data were processed

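Total RNA from Drosophila melanogaster ovaries was sequenced in 4 libraries, 2 from a control knockdown of the eye-colour gene white (white-embKD) and 2 from a knockdown of piwi (piwi-embKD). Per the labels' protocols, flies carried a daughterless (da) GAL4 driver, a temperature-sensitive GAL80 under vasa control and a hairpin against one of the 2 genes. They were kept at 18 °C, and embryos were moved to 28 °C to switch on RNA interference. RNA was extracted with TRIzol, 4 µg per library was depleted of ribosomal RNA, and paired reads of 150 nt were obtained on an Illumina NextSeq. The series' design text and the labels describe the pair in each group as independent biological replicates. Groups and replicate numbers were taken from the sample titles.

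The authors deposited 1 table per library with a signal value for each of 29637 targets. Per the file headers and names, the deposited signal is the effective count estimated by eXpress, which shares out fragments that fit several targets, multiplied by a normalization factor. Bowtie2, STAR, Cufflinks and the genome build dm3 are named in the submitters' processing notes, with no role or version. The annotation, any filter, the strand setting and the source of the normalization factor are not given in the sources used here. Because shared fragments were divided by a model, values of near-identical copies, such as the Hsp70 genes, are uncertain, and so are those of overlapping or antisense genes.

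The deposited columns summed to 989279 and 970339.8 in white-embKD replicates 1 and 2, and to 1017515 and 1004549 in piwi-embKD replicates 1 and 2. The smallest values in each column were whole multiples of a single step, and this step was taken as the last decimal place that eXpress writes (1e-06 of a count), which is an assumption. The value of 1 effective count was then 0.0494 and 0.0504 in the white libraries and 0.0628 and 0.0611 in the piwi libraries. Depth on that basis was 20025084 and 19271510.0 effective counts in the white libraries and 16194219 and 16445363 in the piwi libraries. A target at 0 could have held up to 3 counts, which is a value of 0.148 and 0.151 in the white libraries and 0.188 and 0.183 in the piwi libraries. These floors cover counting error only. Between 3.76% and 4.18% of the values worth 0.5 to 20 effective counts came out whole, so the values were not treated as whole reads and no count test was run.

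Of the 29637 targets, 126 were transposon consensus sequences and 29511 were transcripts. Transcript accessions were matched to gene symbols with an NCBI RefSeq gene table of the Release 6 assembly, which named 28560 transcripts (96.8%) from 14766 genes. Values were summed per gene. The 951 transcripts with no match kept their own row and held 0.63% to 0.81% of each library. The table's assembly is not the authors' build, so it served for names, for the order of neighbouring genes and for the chromosome arm of each gene, and no coordinate is given.

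The groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 0.995), where the pseudocount of 0.995 is the mean column total divided by 1e+06. Features with a mean of at least 0.995 were tested, which left 8132 features: 7772 genes, 107 transposon families and 253 unmatched transcripts. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 8132 features, and a call needed an adjusted p under 0.05. This is the branch written for normalized values in a design that covered either unit. Log2 fold changes are piwi-embKD minus white-embKD on the log2(value + 0.995) scale and understate the change of features at low levels. Means are given ± SD over 2 libraries. In 5 simulated runs of the piwi-embKD against white-embKD comparison over 8132 features, of which 200 were changed, 60.6% of 2-fold and 84.6% of 4-fold changes were recovered and 4.6% of the calls were false. These runs gave both groups the same spread and drew features independently. In the data the piwi pair differed more than the white pair and genes moved together, so these rates may not hold there.

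Lists of genes were fixed before the data were examined. They covered the piRNA pathway, heterochromatin and its histone methylation, siRNA and miRNA machinery, germline, germline stem cell niche signalling, somatic follicle cells, vitelline membrane, chorion, muscle, fat body, gut, spermatheca and oviduct, blood cells, nerve, testis, heat shock, DNA damage, apoptosis, cell cycle, antimicrobial immunity, JAK-STAT stress, sex determination, detoxification, cytosolic ribosomal proteins, and transposons by class and by the tissue known to control them. Each list with at least 3 tested members was tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, with adjustment over the 27 lists tested. Camera with an estimated correlation and fry were alternatives. Counts of members are given over all features and adjusted over the list alone. The fixed lists of piRNA clusters and of mitochondrially encoded genes were not analysed here, and neither were 28 listed symbols in all that found no match.

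The genes named were set by a rule fixed before the data were examined: piwi and white, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose libraries did not overlap between groups, the same for transposon families, and up to 4 members of each list with the smallest p. The families copia, FB and TART-C, the genes eEF1alpha1, Hsp26, fs(1)N, fs(1)M3, Jon99Ciii and alphaTry, and the genes in the other observations that fall outside this rule were chosen after their values were seen. The mean log2 changes of list groups were compared by two-sided permutation tests across genes or families with 100000 resamples, or exactly where a group held fewer than 10, and shares by Fisher's exact test, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Plots were drawn with matplotlib 3.10.9.

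Within-group pairs were compared for duplication. Over targets of at least 100 counts, the squared difference was 30.4 times the counting variance between the white libraries and 43.1 times between the piwi libraries on average (medians of 1.98 and 7.27), so both pairs were kept as separate replicates. The labels name no sequencing batch, and each group holds 2 libraries, so no split by batch was possible. Alternatives covered the pseudocount (0.1 and 5 times the main one), the filter (none, and 5 times the main one), the scaling (median of ratios, and the total over annotated genes), limma without the trend, transcripts left unsummed, the replicate number as a block, each library left out in turn, and the threshold (adjusted p under 0.1, and a 2-fold minimum). Counts without the listed gut, eggshell, muscle and follicle cell genes, and for genes with a mean of at least 20 times the filter, were added after the data were seen.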

Results

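The series asked whether Piwi, the nuclear Argonaute protein of the piRNA pathway, is needed in the embryo for transposons to be held down later in the adult ovary. RNA from adult ovaries was measured in 2 white-embKD libraries, in which the embryonic hairpin was directed at a gene outside the pathway, and in 2 piwi-embKD libraries. Depth, inferred from the smallest step between values, was 20025084 and 19271510.0 effective counts in the white libraries and 16194219 and 16445363 in the piwi libraries. Levels are normalized effective counts, which summed to between 970339.8 and 1017515 per library. The gene eEF1alpha1, a translation elongation factor, had the highest level of any gene in all 4 libraries, and the 10 most abundant targets took 4.15% to 4.72% of each. Small nucleolar and small nuclear RNA genes took 1.09% and 0.38% of the white libraries and 0.99% and 0.57% of the piwi libraries. Across features the white libraries correlated at r = 0.995 and the piwi libraries at r = 0.976 on the log2 scale, where features are not independent replicates.

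The targets of the hairpins were read first. The piwi transcript (RefSeq NM_057527) stood at 410.0 and 401 in the white libraries and at 238 and 121 in piwi-embKD replicates 1 and 2, which is 58.5% and 29.9% of the white mean. The means were 406 ± 6.02 and 179 ± 82.3 (SD, n = 2 each), and both piwi libraries lay below both white libraries. In limma the log2 change was −1.25 with a standard error of 0.29 and an adjusted p of 0.057, so the difference did not pass the threshold. The piwi libraries differed from each other, and the change was −1.73 without piwi-embKD replicate 1, against −0.77 without piwi-embKD replicate 2. It passed in both of these fits, whose spread came mostly from the white pair. It also passed with the stricter filter (limma adjusted p = 0.0431) and with the replicate block (0.00129). The white gene (w, RefSeq NM_057439) was low throughout, at 1.35 and 1.19 in the white libraries and 3.34 and 2.87 in the piwi libraries (log2 change 0.86 ± 0.24 SE, limma adjusted p = 0.101). It passed without piwi-embKD replicate 1 (0.77, limma adjusted p = 0.0317) or replicate 2 (0.94, 0.0286) and without the trend (0.0235). The knockdown was induced in embryos and the RNA came from adult ovaries. The labels give 18 °C for maintenance and 28 °C for embryos. They do not say whether the flies were returned to 18 °C before dissection, so RNA interference that went on in the adult ovary is not excluded. GAL80, which holds GAL4 back, was under control of vasa, a germline gene, and the tissue in which each driver acted is not given. RNA interference in somatic follicle cells is therefore not excluded at either temperature, and it was not tested.

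**Figure D1:**
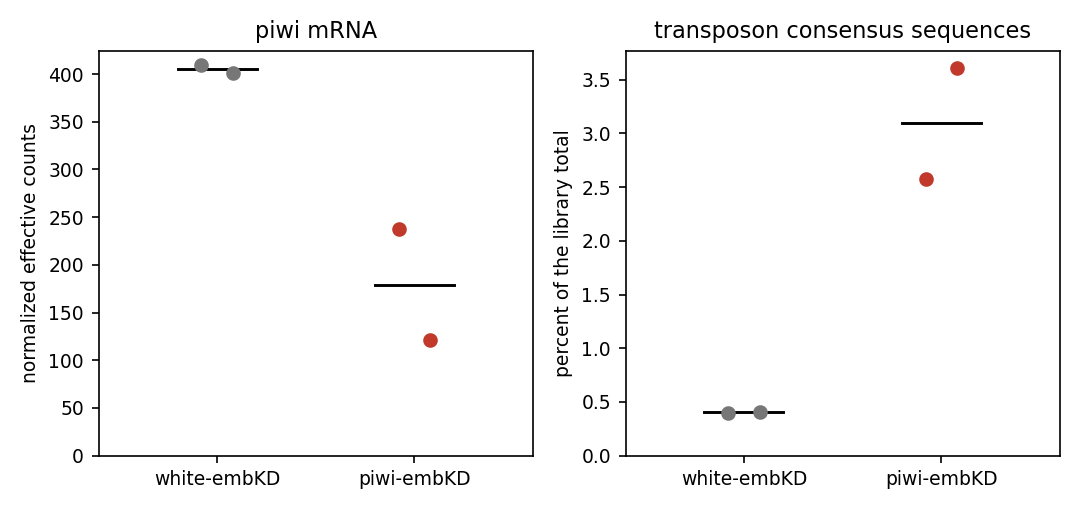
Level of piwi in normalized effective counts (left) and share of each library that came from transposon consensus sequences in percent (right), with 1 point per library and a bar at each group's mean. Both piwi-embKD libraries lie below both white-embKD libraries for piwi (238 and 121 against 410.0 and 401) and above them for transposons (2.58% and 3.61% against 0.40% and 0.41%).

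Transposon RNA was far higher in the piwi-embKD ovaries. Transposon consensus sequences took 0.40% and 0.41% of the white libraries and 2.58% and 3.61% of piwi-embKD replicates 1 and 2, means of 0.405% ± 0.007 and 3.10% ± 0.73 (SD, n = 2 each), a 7.64-fold difference. Of 107 families tested, 61 rose and 0 fell, with 77 higher and 0 lower when adjusted over the list alone, and at an unadjusted p under 0.05 limma placed 80 higher and 0 lower. Among the 61, the rise on the fitted log2 scale was at least 2-fold for 50 and at least 10-fold for 14. For the summed share, an exact permutation test of 2 libraries against 2 cannot give a p below 0.333.

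The largest rise was that of mdg3, an LTR retrotransposon, which went from 30.2 and 30.5 in the white libraries to 4408 and 4854 in the piwi libraries, a 153-fold difference of means (log2 change 7.21 ± 0.09 SE, limma adjusted p = 1.47e-06). The LTR element 3S18 rose from 70.9 ± 5.77 to 5027 ± 2554 (log2 change 6.03 ± 0.32 SE), with piwi-embKD replicate 2 at 6832 and replicate 1 at 3221. The LTR elements blood, Burdock, Transpac and GATE rose by log2 changes of 5.32, 5.21, 4.9996 and 4.80, and copia, the most abundant family in both white libraries, rose from 1620.1 ± 122 to 3883 ± 887. In the piwi libraries mdg3 led in replicate 1 and 3S18 in replicate 2, and the 10 most abundant families held 81.1% and 84.3% of all transposon signal, against 71.3% and 74.0% in the white libraries.

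All 5 measured telomeric retrotransposons, which build the fly's chromosome ends, rose, and 5 did so when adjusted over the list alone. HeT-A went from 85.1 ± 7.93 to 2402 ± 344, TAHRE from 21.8 ± 5.48 to 1288 ± 57.0, TART-A from 4.82 ± 0.27 to 306 ± 23.6 and TART-B from 2.17 ± 0.40 to 262 ± 40.6 (SD, n = 2 each). TART-B had a log2 change of 6.37 ± 0.16 SE (limma adjusted p = 2.19e-05), and TART-C rose by 3.06. The list's median was 5.72 (limma camera adjusted p = 4.02e-10), with an adjusted p = 0.183 with an estimated correlation.

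Families of every class rose. Of 55 LTR families 38 rose (42 adjusted over the list alone), with a median log2 change of 1.10 and HMS-Beagle at 3.91. Of 34 LINE families 16 rose (23 adjusted over the list alone), with a median of 0.84. Of 17 DNA transposon families 6 rose (11 adjusted over the list alone), with a median of 0.60, among them pogo (2.99), Bari1 (1.82) and S-element (1.03). The call of S-element was lost without white-embKD replicate 1 or replicate 2, where its log2 change was 1.05 and 1.01. Leaving out each library in turn gave 3 to 9 DNA families. The P-element, a DNA transposon, stood at 0.37 and 0.21 in the white libraries and 20.8 and 14.4 in the piwi libraries (log2 change 3.84 ± 0.25 SE). The remaining family that rose was the foldback element FB, at 1.22. Limma's camera gave adjusted p-values of 7.03e-40 for all transposons (median 0.95), 2.86e-30 for LTR, 7.8e-19 for LINE and 1.55e-08 for DNA families, and for all 4 the adjusted p = 0.183 with an estimated correlation. The share that rose was 69.1% of LTR, 47.1% of LINE and 35.3% of DNA families, and after adjustment over the 5 comparisons of transposon groups none of the differences passed (LTR against LINE, Fisher's exact p = 0.0467, adjusted 0.0584; LTR against DNA, p = 0.0214, adjusted 0.0535; LINE against DNA, p = 0.552, adjusted 0.552).

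Families known to be controlled in the germline rose by more than those known to be controlled in follicle cells. Of 29 germline-controlled families 21 rose (24 adjusted over the list alone), with a median log2 change of 1.90, and of 21 follicle-cell-controlled families 13 rose (15 adjusted over the list alone, and 8 to 15 when each library was left out), with a median of 0.89. Among the follicle group, gypsy went from 11.4 ± 1.33 to 95.6 ± 0.20, Tirant from 74.0 ± 9.78 to 828 ± 216, Idefix from 5.85 ± 0.95 to 41.9 ± 3.87 and Quasimodo from 10.3 ± 1.31 to 34.4 ± 3.21. Camera adjusted p-values in limma were 1.77e-23 for the germline list and 7.7e-13 for the follicle list, both with an adjusted p = 0.183 with an estimated correlation. The mean log2 change was 2.79 for germline-controlled and 1.14 for follicle-cell-controlled families, and the difference of 1.65 had a two-sided permutation p of 0.00423 across families (adjusted 0.0212 over 5 comparisons). Without the telomeric families the difference was 1.16 and did not pass (permutation p = 0.0325, adjusted 0.0542).

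Of the 46 families not called, 36 were higher in both piwi libraries than in both white libraries, and 19 further families lay below the filter. The count of 61 was 27 with no filter on low values and 28 with transcripts left unsummed, and it ran from 41 to 72 when each library was left out in turn.

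**Figure D2:**
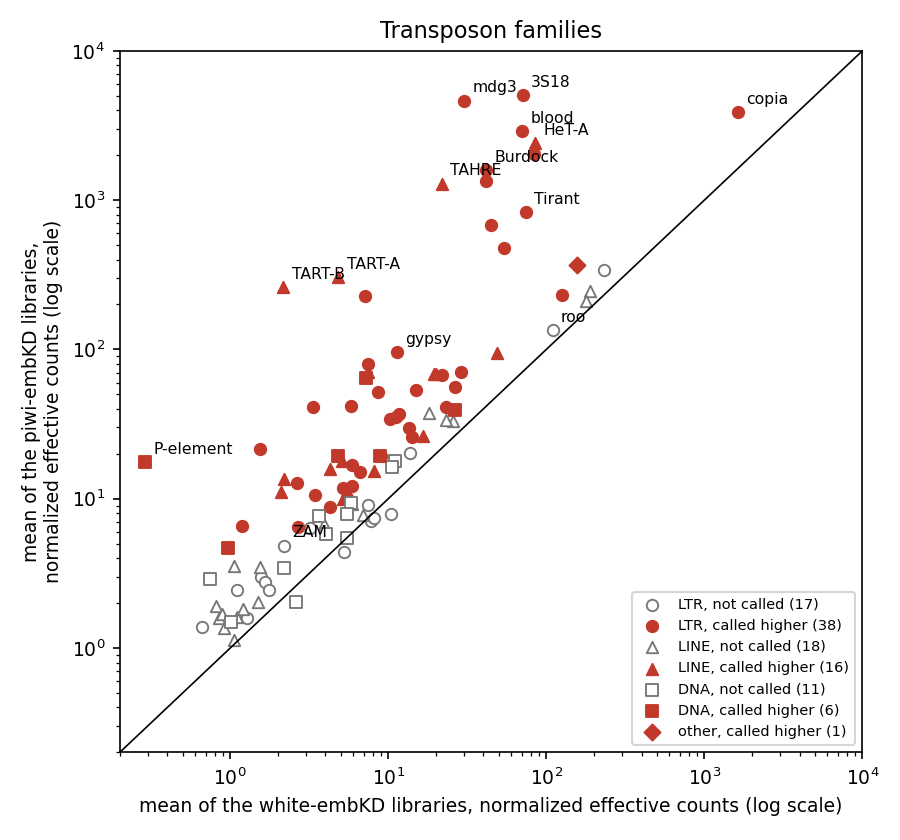
Mean level of each of 107 transposon families in white-embKD (x axis) and piwi-embKD (y axis), in normalized effective counts on log scales, with 1 symbol shape per class, filled symbols for the 61 families that rose and a line of equality. The families that rose lie above the line, farthest for mdg3, TART-B and 3S18.

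Among protein-coding and other genes, 346 rose and 125 fell in piwi-embKD ovaries, 471 of 7772 tested (6.1%). Each group carried its own hairpin, so a difference between the 2 lines cannot be told apart from an effect of the piwi knockdown. The largest rise on the fitted log2 scale was that of hiw (RefSeq NM_078604), which encodes the ubiquitin ligase Highwire, known for its part at synapses. It went from 0.83 and 0.85 in the white libraries to 80.3 and 123 in the piwi libraries, a 122-fold difference of means (log2 change 5.78 ± 0.22 SE, limma adjusted p = 0.000118). CG30345 rose from 9.33 ± 1.17 to 90.02 ± 31.6, Fcp3C, a follicle cell protein, from 6.98 ± 1.12 to 65.6 ± 6.58, and CG14187 from 2.11 ± 0.39 to 23.6 ± 3.93 (SD, n = 2 each).

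Several of the largest rises began near the floor in the white libraries. CG18302 was at 0.10 and 0.21 in the white libraries and 20.3 and 33.3 in the piwi libraries, and CG14636 at 0.05 and 0.36 against 8.81 and 9.74. CG12971 held 2.0 effective counts over both white libraries and CG32437 and alpha-Man-Ic, a mannosidase gene, 4.6 each, while their piwi means were 22.1, 21.6 and 19.9. CG42704 was listed at 0 in both white libraries and at 4.17 and 12.9 in the piwi libraries. The fitted log2 changes of these 6 genes, 4.56 for CG18302, 3.11 for CG14636, 4.41 for CG12971, 4.34 for CG32437, 4.23 for alpha-Man-Ic and 3.09 for CG42704, depend on the pseudocount.

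Several of the largest falls were in genes known to encode digestive enzymes. CG12374 fell from 40.6 ± 0.24 to 1.34 ± 1.78 (log2 change −4.41 ± 0.52 SE, limma adjusted p = 0.00672), and the lysozyme genes LysD and LysB fell by log2 changes of −3.88 and −2.70. The serine protease genes Jon25Bii and Jon25Bi fell by −3.34 and −3.33, and CG5107, the maltase gene Mal-A6 and CG6295 by −3.33, −3.18 and −2.52. The calls of CG5107 and Mal-A6 were lost with the smaller pseudocount (limma adjusted p = 0.0936 and 0.0692), and that of CG6295 without white-embKD replicate 1 (0.0581) or replicate 2 (0.0587). In these 8 genes piwi-embKD replicate 2 stood between 0 and 0.13 and replicate 1 between 0.17 and 2.60. The other 2 were Syt4, a synaptotagmin gene, at 12.8 and 13.3 in the white libraries and 0.29 and 0 in the piwi libraries (log2 change −3.63), and Pde6, a phosphodiesterase gene, at 9.11 and 7.86 against 0.73 and 0.65 (log2 change −2.49).

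At an unadjusted p under 0.05 limma placed 1892 genes, and among all genes tested 58.9% had groups of libraries that did not overlap, where chance gives 33.3%. The count of 471 depended on the libraries and the filter: it was 174 (153 higher) without white-embKD replicate 1, 160 (138 higher) without white-embKD replicate 2, 2698 (1234 higher) without piwi-embKD replicate 1, 1416 (762 higher) without piwi-embKD replicate 2, 74 with no filter on low values and 59 with transcripts left unsummed. Without piwi-embKD replicate 1 more genes were lower (1464) than higher.

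Eggshell genes rose together. Of 13 vitelline membrane genes, which encode the inner eggshell layer, 11 rose (11 adjusted over the list alone) with a median log2 change of 2.15. Vm32E went from 60.2 ± 8.90 to 358 ± 33.9, Vm26Ab from 22.9 ± 0.09 to 106 ± 13.5, Vm26Ac from 11.5 ± 1.07 to 64.0 ± 8.96 and psd from 21.3 ± 1.18 to 107 ± 17.625 (SD, n = 2 each). The 2 members that were not called, fs(1)N and fs(1)M3, had log2 changes of 0.18 and −0.19. All 9 chorion genes, which encode the outer layer, rose (9 adjusted over the list alone), with a median of 1.47, and Cp18 went from 245 ± 15.8 to 829 ± 49.4, Cp16 from 182 ± 3.56 to 511 ± 14.3, Cp19 from 394 ± 27.3 to 1094 ± 122 and Cp15 from 583 ± 49.8 to 1375 ± 50.7. Limma's camera gave an adjusted p of 8.09e-11 for vitelline membrane genes (adjusted p = 0.387 with an estimated correlation) and 4.79e-09 for chorion genes (adjusted p = 0.265 with an estimated correlation).

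Markers of the somatic follicle cells, which make the eggshell, rose in 6 of 11 cases (8 adjusted over the list alone, and 3 to 10 when each library was left out), with a median log2 change of 0.73. The yolk protein genes led: Yp1 went from 459 ± 17.59 to 1100.5 ± 8.75, Yp3 from 255 ± 6.81 to 599 ± 26.0 and Yp2 from 626 ± 5.29 to 1417 ± 50.9. The transcription factor gene tj, which marks follicle cells, went from 16.5 ± 0.20 to 32.2 ± 3.18. Its call was lost without white-embKD replicate 1 or replicate 2, where the log2 change was 0.93 and 0.91. The list's camera adjusted p in limma was 4.6e-07, with an adjusted p = 0.183 with an estimated correlation.

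Muscle genes, which ovaries carry in their sheath, rose in 4 of 15 cases (9 adjusted over the list alone, and 0 to 11 when each library was left out). The myosin gene Mhc went from 15.2 ± 1.15 to 29.4 ± 2.67, the actin gene Act57B from 21.8 ± 2.67 to 39.3 ± 2.73, sls from 57.0 ± 1.54 to 86.9 ± 10.3 and Prm from 4.36 ± 0.15 to 8.77 ± 0.94 (SD, n = 2 each). None of these 4 passed without either white library, where their limma adjusted p-values lay between 0.0579 and 0.382, and sls was also lost without the trend (0.0691) and Prm with the stricter filter (0.0534). The median was 0.59 (limma camera adjusted p = 1.59e-06, and an adjusted p = 0.469 with an estimated correlation).

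Gut genes, which encode secreted digestive enzymes, were lower. Of 13 measured, 3 fell (2 to 13, and 0 to 2 higher, when each library was left out), Jon25Bii, Jon25Bi and epsilonTry (3.17 ± 0.25 to 0.34 ± 0.48), and 6 did so when adjusted over the list alone. The call of epsilonTry was lost without white-embKD replicate 1 (limma adjusted p = 0.273) or replicate 2 (0.389), with median-of-ratios scaling (0.052) and with the smaller pseudocount (0.112). The trypsin gene betaTry, at 40.0 ± 4.37 and 4.84 ± 6.53, did not pass (log2 change −3.52, limma adjusted p = 0.0764). It did so with the larger pseudocount (−2.37, 0.0279), with the replicate block (0.000759) and without piwi-embKD replicate 1 (−5.07, 4.24e-05) or replicate 2 (−1.97, 0.000926). Summed over the list, the level was 278 and 258 in the white libraries, 207 in piwi-embKD replicate 1 and 0.97 in piwi-embKD replicate 2. The median log2 change was −2.45 (limma camera adjusted p = 4.73e-05, and an adjusted p = 0.521 with an estimated correlation), but −0.58 without piwi-embKD replicate 2 and −3.97 without piwi-embKD replicate 1.

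Few genes of the piRNA pathway passed the test. Of 34 measured, 0 rose and 2 fell (4 adjusted over the list alone, and 0 to 3 higher and 0 to 17 lower when each library was left out): armi, an RNA helicase gene, from 317 ± 3.06 to 213 ± 11.4 (log2 change −0.57 ± 0.09 SE, limma adjusted p = 0.0181) and rhi, which encodes the chromatin protein Rhino of dual-strand clusters, from 64.3 ± 0.47 to 45.9 ± 2.59 (−0.48 ± 0.10 SE, limma adjusted p = 0.0475). At an unadjusted p under 0.05 limma placed 1 higher and 7 lower. AGO3, which takes part in the ping-pong cycle of piRNA amplification, stood at 422 ± 28.6 and 264 ± 57.6 and did not pass (log2 change −0.69, limma adjusted p = 0.0566). It did so with the stricter filter (0.0453), with the replicate block (0.00454) and without piwi-embKD replicate 1 (−0.92, 0.00117) or replicate 2 (−0.47, 0.0152). The list's median was −0.16 (limma camera adjusted p = 0.0214, and an adjusted p = 0.564 with an estimated correlation). The list includes piwi, the hairpin's own target, whose log2 change of −1.25 was its lowest. This gene is among the 7 lower at an unadjusted p under 0.05, and the list was not tested without it. The calls of armi and rhi were lost without each white library in turn, but their log2 changes hardly moved. They were −0.58 and −0.47 without white-embKD replicate 1 and −0.56 and −0.49 without white-embKD replicate 2. The call of rhi was also lost with median-of-ratios scaling (limma adjusted p = 0.0506) and without the trend (0.0726). Without piwi-embKD replicate 2 the list's median was −0.05 and its camera call was lost.

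Heat shock genes went both ways, with 3 of 13 higher and 2 lower (6 and 3 adjusted over the list alone, and 3 to 6 higher and 1 to 4 lower when each library was left out). The small heat shock genes Hsp22 and Hsp26 fell, Hsp22 from 35.2 ± 1.01 to 13.9 ± 0.81 and Hsp26 by a log2 change of −0.59. The call of Hsp26 was lost without white-embKD replicate 1 or replicate 2, where its log2 change was −0.54 and −0.64. Hsp70Bb and Hsp70Bbb, whose values were identical and cannot be told apart, rose from 3.50 ± 0.36 to 13.7 ± 0.12, and Hsp70Bc from 2.37 ± 1.30 to 11.4 ± 1.34. The list's median was 0.34, and camera in limma gave an adjusted p of 0.0759. The list passed without white-embKD replicate 2 (median 0.37, camera adjusted p = 0.0181) and with transcripts left unsummed (median 0.41, camera adjusted p = 0.0335).

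Antimicrobial immunity genes had a median log2 change of 1.01, and 1 of 9 rose (3 adjusted over the list alone, and 0 to 6 higher and 0 to 1 lower when each library was left out). That was the defensin gene Def, listed at 0 in both white libraries and at 7.51 and 2.01 in piwi-embKD replicates 1 and 2, a call lost without white-embKD replicate 1 (limma adjusted p = 0.12) or replicate 2 (0.141), with the larger pseudocount (0.098), with either other scaling (0.0609 and 0.0549) and without the trend (0.0696). PGRP-LB had a log2 change of 1.01, Drs 1.32 and AttA 1.09, and none of these passed. The list's camera adjusted p in limma was 0.00651, with an adjusted p = 0.521 with an estimated correlation, and 0.242 without piwi-embKD replicate 1, where the median was 0.58.

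Cytosolic ribosomal protein genes and cell cycle genes moved as lists by small amounts, with no member called on all 4 libraries. Leaving out each library in turn gave 0 to 14 higher and 0 to 1 lower ribosomal protein genes. It gave 0 to 1 higher and 0 to 12 lower cell cycle genes, with 0 of either without each white library. Of 85 ribosomal protein genes 0 were called by limma over all features and 0 adjusted over the list alone, with 10 higher and 0 lower at an unadjusted p under 0.05. RpL8 stood at 861 ± 24.96 and 1108 ± 19.8, and RpL23A, RpL3 and RpLP1 had log2 changes of 0.47, 0.36 and 0.30. The median was 0.14 (limma camera adjusted p = 0.000116, and an adjusted p = 0.571 with an estimated correlation), and without piwi-embKD replicate 1 it was 0.03 (camera adjusted p = 0.0694). Of 20 cell cycle genes 0 were called by limma over all features and 0 adjusted over the list alone, with 0 higher and 7 lower at an unadjusted p under 0.05. Mcm5 stood at 344 ± 15.5 and 269.9 ± 0.57, and CycA, twe and fzr had log2 changes of −0.34, −0.35 and −0.28. The cell cycle median was −0.20 (limma camera adjusted p = 0.00187, and an adjusted p = 0.486 with an estimated correlation).

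Lists of chromatin, germline and small RNA genes did not pass at the preset correlation on all 4 libraries. Of 18 heterochromatin genes limma called 0 (0 adjusted over the list alone, and 1 higher and 4 lower unadjusted), with a median of −0.16 and a camera adjusted p of 0.0759. The list passed with no filter on low values (camera adjusted p = 0.0164) and with transcripts left unsummed (0.0432). Leaving out each library in turn gave 0 to 1 higher and 0 to 8 lower. HP5, HP1b, HP4 and Su(var)3-3 had log2 changes of −0.39, −0.29, −0.45 and −0.27. Of 20 germline genes limma called 0 (0 adjusted over the list alone, and 3 higher and 6 lower unadjusted; 0 to 5 higher and 0 to 4 lower when each library was left out), with a median of −0.05 (camera adjusted p = 0.574). The genes pum, pgc, otu and grk had log2 changes of 0.32, 0.33, 0.35 and −0.36. Of 8 siRNA and miRNA genes limma called 0 (0 adjusted over the list alone and 0 unadjusted, and 0 to 1 higher when each library was left out), and their median of 0.003 and mean of −0.016 differed in sign (camera adjusted p = 0.875). Loqs, r2d2, AGO2 and drosha had log2 changes of −0.25, −0.19, 0.22 and 0.09. Of 13 genes of germline stem cell niche signalling limma called 0 (3 higher adjusted over the list alone, and 5 higher and 3 lower unadjusted), with a median of 0.22 (camera adjusted p = 0.123). The genes N, dpp, gbb and dome had log2 changes of 0.37, 0.83, 0.59 and 0.55. Without piwi-embKD replicate 1 limma called 7 of the 13 higher and 3 lower. Without replicate 2 it called 2 higher and 0 lower, and without each white library 0.

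Stress and other lists did not pass camera either. Leaving out each library in turn gave 0 to 3 higher and 0 to 7 lower DNA damage genes, 0 to 1 and 0 to 3 apoptosis genes, 0 to 1 and 0 to 1 JAK-STAT stress genes, 0 to 2 and 0 to 2 sex determination genes, and 0 to 1 and 0 to 4 detoxification genes. Of 19 DNA damage genes limma called 0 (0 adjusted over the list alone, and 2 higher and 6 lower unadjusted; median −0.17, camera adjusted p = 0.156), with egr at 0.88, hid at 1.22, Irbp at −0.35 and RnrS at −0.35. Of 7 apoptosis genes limma called 0 (1 higher and 1 lower adjusted over the list alone, and 1 higher and 2 lower unadjusted). Their median of −0.07 and mean of 0.04 differed in sign, and camera placed them lower (adjusted p = 0.477), with Dronc at −0.40, Dark at −0.32 and Drice at −0.17. Of 3 JAK-STAT stress genes limma called 0 (2 lower adjusted over the list alone and 2 lower unadjusted; median −0.38, camera adjusted p = 0.171), with vir-1 at −0.38, TotA at −0.84 and Socs36E at 0.29. Of 9 sex determination genes limma called 0 (1 higher adjusted over the list alone and 1 higher unadjusted; median 0.00, camera adjusted p = 0.574), with fru at 0.86, tra2 at −0.24, vir at 0.40 and dsx at 0.47. Of 8 detoxification genes 1 fell (1 higher and 1 lower adjusted over the list alone), the cytochrome P450 gene Cyp6a9, from 11.96 ± 0.55 to 5.995 ± 0.72 (SD, n = 2 each). The call of Cyp6a9 was lost without white-embKD replicate 1 or replicate 2, where its log2 change was −0.85 and −0.94. The genes Cyp12d1-p, GstD2 and GstD1 had log2 changes of 0.45, 0.42 and −0.15 (list median −0.09, camera adjusted p = 0.868).

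Markers of other tissues that a dissection can carry were mostly too few or too low to test. Of 3 blood cell genes limma called 0 (2 higher and 1 lower adjusted over the list alone, and likewise unadjusted), with srp at 1.14, Pxn at 0.72 and crq at −0.30 (camera adjusted p = 0.268). All 3 were called without piwi-embKD replicate 1 and 1 without replicate 2. Fat body, nerve, spermatheca and oviduct, and testis lists had 2 tested members each and no list test, and limma called 0 in each. It called 0 to 1 when each library was left out. Adjusted over the list alone, 1 spermatheca and oviduct gene was higher and 1 lower, as at an unadjusted p under 0.05, and the other 3 lists had 0 in both. The log2 changes were 0.15 for apolpp and −0.03 for fit of the fat body, 0.59 for futsch and 0.30 for elav of nerve, 0.43 for Oamb and −0.29 for Hr39 of the oviduct, and 0.35 for fzo and −0.02 for Phf7 of testis. Of the 27 lists tested, 16 passed camera at the preset correlation and 0 with an estimated correlation.

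**Figure D3:**
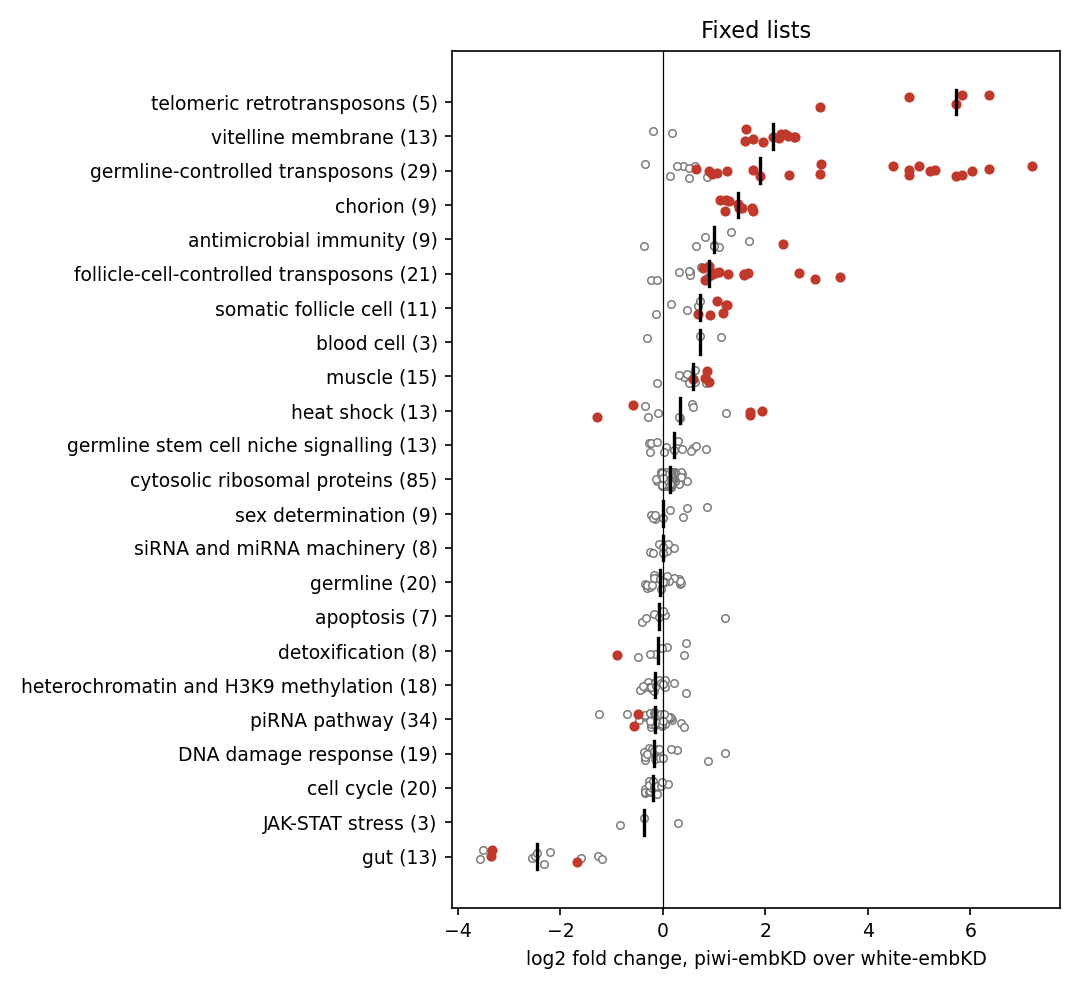
Log2 fold change of each tested member of the fixed lists (x axis), with 1 row per list and its number of tested members, filled points for members past the threshold and a bar at each list's median. Medians run from −2.45 for gut genes to 5.72 for telomeric retrotransposons, with vitelline membrane genes at 2.15 and chorion genes at 1.47.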

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

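The alternatives were fixed before the data were examined, except the minimum of 20 times the filter and the omission of listed genes, which were chosen after seeing the data. Against 471 genes (346 higher, 125 lower), limma called 74 (53 and 21) with no filter, all 74 also among the 471, 59 (51 and 8) with transcripts unsummed, 872 (571 and 301) at an adjusted p under 0.1, 268 (219 and 49) with at least a 2-fold change, and 262 (184 and 78) with a mean of at least 20 times the filter. Without the listed gut, eggshell, muscle and follicle cell genes it was 438. With no filter 11323 genes were tested and limma's prior degrees of freedom went from 4.21 to 1.97, and with transcripts unsummed to 3.03; beyond that the cause was not tested. Higher calls made up 73.5% here, 76.4% with median-of-ratios scaling, 70.6% with scaling to the gene total and 86.4% unsummed. The share was 87.9% and 86.2% without white-embKD replicates 1 and 2, 53.8% without piwi-embKD replicate 2 and 45.7% without piwi-embKD replicate 1, where lower calls (1464) outnumbered higher ones (1234). Transposon calls went from 61 to 27 with no filter and 28 unsummed, and the 16 list calls to 0 with an estimated correlation. Of the 121 genes and families followed by name, 21 lost their call with no filter, 27 of 120 unsummed and 12 without each white library in turn. Calls were gained by 27 without piwi-embKD replicate 2 and 40 without piwi-embKD replicate 1, with none gained without a white library. Further gains were egr, hid, Drs, srp and fru with the replicate block (adjusted p = 0.0434, 0.0022, 0.0375, 0.00316 and 0.0392), egr, Pxn, dpp, gbb and fru without the trend (0.0204, 0.031, 0.0215, 0.0405 and 0.0291), and egr and fru with the larger pseudocount (0.0439 and 0.0472). The rotation test fry, which does not compare a list with other genes, kept every transposon list, vitelline membrane, chorion and follicle cell lists. It lost gut (adjusted p = 0.222), muscle (0.0907), piRNA pathway (0.23), cell cycle (0.132), ribosomal (0.256) and antimicrobial lists (0.284), and gained heat shock (0.0262) and blood cell lists (0.00609). Leaving out each library in turn gave 160 to 2698 genes (138 to 1234 higher, 21 to 1464 lower), 41 to 72 transposon families and 14 to 17 lists. The log2 change then ran from −1.73 to −0.77 for piwi and from 0.77 to 0.94 for w. An arm left with 1 library was assumed to vary like the other arm. Without a white library the calls were fewer (174 and 160), and without a piwi library more (2698 and 1416), since the spread then came mostly from the closer white pair. Every transposon family called under any alternative was higher, except Tc3, lower without piwi-embKD replicate 1 (−0.77, adjusted p = 0.0311).

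The piwi value of −1.25 was past the threshold with the stricter filter (adjusted p = 0.0431) and the w value of 0.86 was so without the trend (adjusted p = 0.0235), without piwi-embKD replicate 1 (0.77, 0.0317) and without piwi-embKD replicate 2 (0.94, 0.0286). With the replicate number as a block limma called 690 genes (490 higher, 200 lower), 469 of the 471 among them, and 65 families, and piwi passed at −1.25 (adjusted p = 0.00129). Deviations of the replicate 1 libraries correlated between the groups at only 0.057 across features. Small nucleolar and small nuclear RNA genes did go with the number. They took 1.09% and 0.99% of white-embKD and piwi-embKD replicate 1, and 0.38% and 0.57% of replicate 2. A batch shared by number is therefore not excluded. Alternatives for piRNA clusters were not run. The piwi libraries were the shallower pair, and genes with a few effective counts in a group were set mostly by the pseudocount.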

Other observations

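The tests of gut tissue, of egg chamber stage and follicle share on eggshell genes, of insertions, of neighbours outside the lists and of chromosome 4 were chosen after the results were seen. So were the count of neighbours with identical values taken once and the comparison of follicle-cell-controlled families with vitelline membrane and chorion genes. The others were chosen before. Genes in the next 3 paragraphs that are outside the naming rule were chosen after their values were seen.

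Other genes changed in piwi-embKD ovaries. The collagen IV genes Col4a1 and vkg, which are neighbours, went from 9.57 ± 0.66 to 30.9 ± 0.53 and from 20.9 ± 0.84 to 47.0 ± 8.27 (SD, n = 2 each). The laminin genes LanA, LanB1 and LanB2 rose by log2 changes of 0.99, 0.86 and 0.99, the calls of LanB1 and LanB2 being lost without white-embKD replicate 2 (limma adjusted p = 0.113 and 0.226) and that of LanB1 also without replicate 1 (0.0975). SPARC, whose product binds collagen IV, had a log2 change of 0.30 and did not pass (limma adjusted p = 0.31). Among the falls, the transporter gene Mrp5 went from 55.8 ± 0.19 to 14.3 ± 0.83, and Arc1 and its neighbour Arc2, relatives of retrotransposon Gag genes, from 343 ± 9.47 to 148 ± 42.8 and from 7.08 ± 1.42 to 2.89 ± 0.27. The call of Arc2 was lost with median-of-ratios scaling (limma adjusted p = 0.0536). It was also lost without white-embKD replicate 1 or replicate 2, where the log2 change was −1.23 and −0.87.

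Genes of the small chromosome 4, much of which is packed as heterochromatin, leaned lower. Of 64 tested, 9 fell and 0 rose, against 116 and 346 on the other chromosomes (Fisher's exact p = 5.25e-06, two-sided, which treats genes as independent). The other chromosomes were not alike. On the X 5 fell and 74 rose, against 24 to 32 falls and 59 to 81 rises on each arm of chromosomes 2 and 3. The 9 on chromosome 4 were mav, PlexB, Cadps, CG11155, unc-13, anne, CaMKI, Eph and Taf3, and mav, a TGF-beta ligand gene, went from 101 ± 6.88 to 37.2 ± 14.9. Only 1 of the 9 calls was kept without white-embKD replicate 1 (PlexB) and 1 without replicate 2 (mav), while all 9 were kept without each piwi library in turn. Those of unc-13 and Taf3 were also lost with median-of-ratios scaling (limma adjusted p = 0.0586 and 0.053). The median of the 64 was −0.25, against −0.02 for lists matched on level, and 0.0% of 10000 such lists had a median as low. In all, 39 of the 64 were lower and 9 higher in both piwi libraries than in both white libraries, and the median ran from −0.30 to −0.18 when each library was left out.

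Genes that changed lay next to each other. Among 7772 tested genes, 71 adjacent pairs were called in the same direction, against a mean of 17.4 and a highest count of 34 in 10000 random placements (permutation p = 0.0001, the smallest these can give). Without any gene on a fixed list the count was 48, against a mean of 14.9 and a highest count of 32 (permutation p = 0.0001, the smallest these can give). Random placement treats genes as independent. Pairs on none of the lists included LysB with LysD, Arc1 with Arc2 and vkg with Col4a1, so related neighbours were not taken out. The gene CG32437 lies between CG12971 and rgn, which also rose (30.5 ± 1.81 to 63.1 ± 16.7), and CG42704 is next to CG42705 and near ct, both of which rose (2.11 and 1.05). The calls of rgn, CG42705 and ct were lost without white-embKD replicate 1 (limma adjusted p = 0.0694, 0.0858 and 0.23) or replicate 2 (0.129, 0.131 and 0.217). The 4 tal reading frames had identical values and stand for a single transcript. They and the identical Hsp70Bb and Hsp70Bbb make 4 of the 71 pairs. With genes of identical values counted once there were 67 pairs (mean of 17.1, highest 34), and 45 outside the lists (mean of 14.7, highest 30), each with a permutation p of 0.0001. Called genes made up like shares of the tested genes on the arms of chromosome 3 (208 of 3376) and elsewhere (263 of 4396), with a Fisher's exact p of 0.774 and an odds ratio of 1.03.

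Gut genes were lower in the piwi libraries, and most of all in piwi-embKD replicate 2. Lower depth does not account for it, since 0.0% of 10000 lists matched on level had a median as low as −2.45 (the median of matched lists was 0.07). In piwi-embKD replicate 2, 13 of 13 measured gut genes were under 5% of their white mean, the highest at 1.61%. Gut tissue carried into the other 3 libraries and not into this one could give this, but the count restates the pattern and does not test it. In piwi-embKD replicate 1 the genes stood between 3.36% (Jon25Bi) and 315% (Jon25Biii) of their white means, so they did not move by a single ratio. Its most abundant genes in the white libraries were Jon99Ciii and alphaTry, at 46.3 and 44.2, and in piwi-embKD replicate 1 these stood at 55.4 and 12.2. Whether gut tissue carried into the white libraries alone may explain the rest cannot be told, because 10 of 13 genes were lower in both piwi libraries and piwi-embKD replicate 1 kept a list sum of 207 against 278 and 258.

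Eggshell genes were higher in both piwi libraries, 20 of 22 past the threshold. A larger share of follicle cells of all stages would raise the follicle cell list as much if specific to those cells. That specificity was not tested. Eggshell genes rose by 0.91 more on the log2 scale (22 against 11 genes, permutation p = 0.0007). The difference was 0.70 to 1.12 when each library was left out. This p is across genes and not across libraries. The genes moved together (estimated correlation of 0.867 for vitelline membrane and 0.379 for chorion genes), so a larger follicle cell share is not excluded. A larger share of egg chambers at the last stages may account for the rise. Chorion genes, which are made last, had a mean change that differed from that of vitelline membrane genes by −0.39 (exact permutation p = 0.212), which decides neither way. The vitelline membrane list includes fs(1)N and fs(1)M3, which were not called and lower its mean. By median, vitelline membrane genes rose more (2.15 against 1.47), which is not the direction that later stages would give. The comparison without fs(1)N and fs(1)M3 was not run, so the question stays undecided. A direct effect of the piwi knockdown on these genes stays open and was not tested.

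Transposons were higher in the piwi libraries. Different insertions in the 2 hairpin lines would put families on both sides if each line gained its own. Instead, 97 families were higher and 1 was lower in both piwi libraries. The direction of the calls was known when this count was chosen, so the count describes the pattern and is no separate test. The count also does not cover a line that gained more insertions than the other. Each group carried its own hairpin, so insertions are not excluded as a cause. For the follicle-cell-controlled families, a larger share of follicle cells would raise each by about as much as a list specific to those cells. The highest rise in the follicle cell list, whose specificity was not tested, was 1.26. Of 21 such families, 7 lay above it (Tirant, gypsy, Idefix, Quasimodo, rover and 2 others), and 6 to 7 did so when each library was left out. A larger share of egg chambers at the last stages, the explanation left open for eggshell genes, could raise them by as much as those genes. The highest rise was 2.57 among vitelline membrane genes and 1.76 among chorion genes, which are made last. Of the 7, Tirant (3.45 ± 0.19 SE) and gypsy (2.97 ± 0.12 SE) lay above 2.57. Idefix (2.65 ± 0.16 SE) lay above 1.76 and within its standard error of 2.57, and the other 4 lay below both. This explanation therefore stays open for the group. The embryonic knockdown and the lower piwi level of the adult ovaries themselves (238 and 121 against 410.0 and 401) were not tested apart. The same holds for RNA interference in adult follicle cells. For insertions in any family, and for the rest of the follicle group, technical explanations remain open.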
